A study of Mus musculus with 8 samples.

How the data were processed

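The samples were follicular helper T (TFH) cells of the memory phase, sorted from the spleens of female C57/Bl6N mice that had been infected with lymphocytic choriomeningitis virus (LCMV). The gate, per the labels' protocols, took CD4-positive, CD44-positive cells that bound the gp66 tetramer, which marks T cells specific for one viral peptide, and that lacked Ly6C and PSGL-1. RNA was isolated with the PicoPure kit and libraries were made with SMART-Seq v4, a full-length cDNA amplification chemistry for very small inputs, per the labels. Each library came from 1 mouse. The groups were 4 control mice and 4 mice given an antibody against ICOS ligand (anti-ICOSL), and the titles carry replicate numbers that the groups do not share, so no samples were paired. What the control mice received, and any batch or date of sequencing, is not given in the sources used here.

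The deposited table held whole-number counts of reads per gene, not normalized, for 47643 Ensembl genes and 8 libraries. Per the submitters' processing notes, the tools were STAR 2.7.0c, FastQC 0.11.4 and featureCounts of Subread 1.6.4, with genome build mm10. The gene annotation and the strand setting of the counting are not given in the sources used here. Counts of overlapping genes on opposite strands are therefore uncertain, and so are those of near-identical copies that share reads. Gene lengths in bases, which the deposited table also held, were not used. Of the Ensembl identifiers, 47224 were found in GENCODE release M21 on the same build, 45100 of them with the same symbol, and coordinates were taken from that annotation.

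Libraries were normalized with TMM factors and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by its robust quasi-likelihood F test, two-sided, on the 15874 genes that passed filterByExpr, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels of genes are given as CPM, counts divided by the TMM-scaled library total and expressed per 1e+06, mean ± SD over the 4 libraries of a group, and fold changes are log2 of anti-ICOSL over control ± the standard error of the fit. For a gene with no read in any library of a group, the fold is a bound against a floor of 3 counts per library. The standard errors come from the variation between replicate libraries. Floors cover counting error only, since reads amplified without molecular identifiers are not independent molecules.

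Before the data were examined, 18 lists of genes of biology and 9 lists of cell type markers were fixed, and the 22 lists with at least 5 tested members were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The cell type lists covered T cells, regulatory T cells, CD8 T and NK cells, B cells, plasma cells, myeloid cells, dendritic cells, erythroid cells and platelets, and stromal and endothelial cells. Total counts, genes detected, shares of counts and the summed CPM of each marker list (scaled by total counts, without TMM factors) were compared by a two-sided exact permutation test over the 70 assignments of the 8 libraries, whose smallest possible p is 0.0286.

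The genes named were fixed by a rule in 3 parts: 18 genes named whatever their result; the genes past the threshold with the largest changes, up to 10 per direction, or, where none passed, the 5 per direction with the smallest p among genes of mean log2 CPM of at least 2 whose groups did not overlap; and up to 4 members of each list of biology with the smallest p. No gene passed, so the second part used its fallback, which sets no condition on the kind of gene and so took in a T cell receptor segment. Some results of the rule and of the marker lists are left out of the text because they need items withheld for evaluation.

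The alternatives tried were DESeq2 1.42.0 size factors, upper-quartile scaling and no scaling factor, no low-count filter and a filter of at least 50 reads in at least 4 libraries, the DESeq2 Wald test, limma-voom with sample weights, a non-robust dispersion, a test against a fold of 1.2, 1 surrogate variable (sva 3.50.0), removal of receptor segments with mitochondrial and haemoglobin genes, each library left out in turn, and an adjusted p threshold of 0.1. Filters at a mean of 20 and of 50 CPM, limma-voom with a variance per group, an exact permutation test of list means, a detection limit of 10 reads, and thinning to the smallest total were added after seeing the data. The edgeR steps were tested on simulated counts for anti-ICOSL against control, with 200 changed genes. At the dispersions of the real genes, over 15129 tested genes, 2% of the genes changed by a fold of 2 and 17% of those changed by a fold of 4 were recovered. At a dispersion of 0.02, over 15829 tested genes, 100% of both were recovered. Both groups were simulated at the same dispersion per gene, while the real groups differed (common dispersion 0.421 in control and 1.39 in anti-ICOSL libraries). Recovery in the real data can therefore differ.

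Depth ran from 42090274 to 50878426 counts per library. No pair of replicates was a duplicate: the chi-square per degree of freedom between replicates, over genes with at least 20 reads in the pair, ran from 143 to 517.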

Results

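RNA was sequenced from virus-specific memory TFH cells, the CD4 T cells that help B cells in follicles, sorted from the spleens of 8 LCMV-infected mice. From day 50 after infection 4 of the mice were given anti-ICOSL, in 4 injections 72 hours apart, and spleens were taken on day 61. The antibody targets the ligand of ICOS, a costimulatory receptor that TFH cells carry. The question was which transcripts differ in memory TFH cells when that ligand is targeted late, after the memory population has formed. Libraries held 42282433 to 50878426 counts in the control group and 42090274 to 45222282 in the anti-ICOSL group. Floors given below cover counting error only, while SDs and standard errors come from the replicate mice.

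Of 27 tested genes of TFH identity, 19 had a negative and 8 a positive fold change after anti-ICOSL. Cxcr5, the chemokine receptor that guides T cells into follicles, was measured at 604 ± 123 CPM in control and 313 ± 27 CPM in anti-ICOSL cells (SD, n = 4 and 4), a log2 fold change of -0.95 ± 0.15. Bcl6, the repressor that specifies the TFH lineage, stood at 109 ± 28.7 against 37.3 ± 23.6 CPM, Pdcd1, which encodes the inhibitory receptor PD-1, at 780 ± 59.1 against 439 ± 157 CPM, and the transcription factor gene Tox2 at 396 ± 107 against 209 ± 36.8 CPM. In the other direction, Bcl2, an inhibitor of apoptosis, stood at 188 ± 30.8 against 355 ± 27.6 CPM, Il7r, the receptor chain for the survival cytokine IL-7, at 450 ± 126 against 804 ± 146 CPM, and Socs1, a feedback inhibitor of cytokine signalling, at 97.3 ± 7.57 against 204 ± 29.4 CPM. For each of these 7 genes every anti-ICOSL library lay on the same side of every control library, yet none passed edgeR's quasi-likelihood test after adjustment over all genes, and the call of the TFH list by camera was lost with an estimated correlation. Socs1 and Bcl2 met a naming rule that requires such separation, and Tox2 was named for its small p, so for them separation adds no support. Over all tested genes 4.81% separated likewise.

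**Figure D1:**
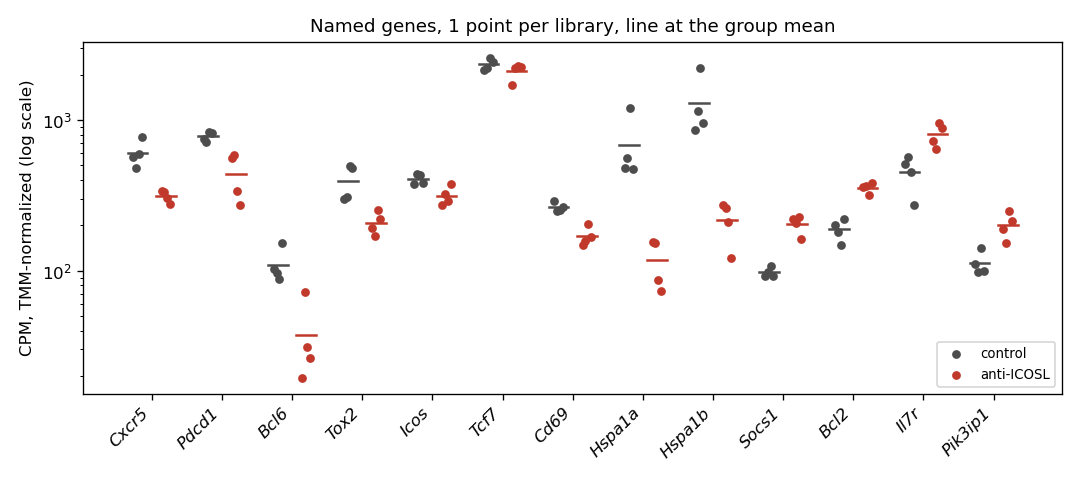
TMM-normalized CPM on a log axis for 13 named genes, with 1 point per library and a line at each group mean (control grey, anti-ICOSL red). Cxcr5 averaged 604 CPM in control and 313 CPM in anti-ICOSL libraries, and Bcl2 averaged 188 and 355 CPM.

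By edgeR, 0 of 15874 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.0864. At an unadjusted p under 0.05 there were 742 genes, 316 higher and 426 lower, where 794 would be met by chance. The DESeq2 Wald test called 183 genes, 53 higher and 130 lower, of which 95 averaged under 10 CPM, and limma-voom called 0. The groups did not overlap for 763 genes, 258 higher and 505 lower, which is 4.81% of those tested against 2.86% by chance. Among the 10245 genes of at least 10 CPM they numbered 181 higher and 249 lower, so much of the excess of lower genes lay in weakly expressed ones.

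The TFH identity list fell relative to all other genes by camera (adjusted p = 0.00398, and adjusted p = 0.343 with an estimated correlation). Its 27 tested members had a median log2 fold change of -0.35, and 7 were lower in every anti-ICOSL library than in every control. Adjusted over the list alone, Cxcr5 and Tox2 passed edgeR's test (adjusted p = 0.00827 and 0.0447), and 0 members passed over all genes. The log2 fold change was -1.55 ± 0.44 for Bcl6, -0.83 ± 0.25 for Pdcd1, -0.93 ± 0.22 for Tox2 and -0.37 ± 0.12 for Icos. Il21, the cytokine gene through which TFH cells act on B cells, stood at 83.2 ± 45.3 against 51 ± 18 CPM, and this gene and the memory-associated transcription factor genes Tcf7 (2340 ± 191 against 2116 ± 268 CPM) and Id3 (208 ± 36.0 against 170 ± 34.4 CPM) overlapped between the groups. The call was lost without anti-ICOSL replicate 9 (adjusted p = 0.185) and without anti-ICOSL replicate 10 (adjusted p = 0.0694, both by camera), and over the 13 alternatives run for lists its adjusted p ran from 0.000737 to 0.343. The anti-ICOSL libraries, in which this list was lower, also held fewer detected genes, 16830 ± 666 against 18950 ± 380.

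Among 17 tested genes of central memory and survival, 11 had a positive and 6 a negative fold change (median 0.05, adjusted p = 0.108 by camera). Bcl2 alone passed when adjusted over the list alone (edgeR adjusted p = 0.00369, and 0.104 over all genes), with a log2 fold change of 0.92 ± 0.14. That of Il7r was 0.84 ± 0.24, and that of Socs1, which no list held, was 1.07 ± 0.15. The DESeq2 test called Socs1, Bcl2 and Il7r (adjusted p = 8.08e-10, 2.67e-07 and 0.0333), and it called Cxcr5 and Tox2 (1.61e-05 and 0.00942) but not Bcl6 (0.0563) or Pdcd1 (0.132). Over the alternatives run for genes these were the lowest values, and the highest adjusted p was 0.461 for Socs1 and Bcl2, 0.552 for Cxcr5, 0.917 for Tox2 and 1 for Il7r, Bcl6 and Pdcd1. Satb1, a chromatin organizer of T cells, overlapped between the groups at 135 ± 27.3 against 182 ± 53.5 CPM.

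Trafficking genes showed no common direction. Of 18 tested genes of the KLF2 and lymphocyte trafficking list, 10 were higher and 8 lower in sign (median 0.15, mean 0.02, camera direction down, adjusted p = 0.931). Cd69, an activation marker that retains cells in tissue, passed when adjusted over the list alone (edgeR adjusted p = 0.023), at 264 ± 19.6 against 169 ± 24.0 CPM and a log2 fold change of -0.64 ± 0.13. Klf2, a transcription factor that maintains lymphocyte recirculation, had a log2 fold change of -0.55 ± 0.26, its target S1pr1 -0.59 ± 0.27, the lymph node homing receptor gene Ccr7 0.22 ± 0.43, and Selplg, which encodes the sorting marker PSGL-1, 0.38 ± 0.17. Of 18 tested FOXO1 targets and PI3K-restrained genes, 6 were higher and 12 lower in sign (median -0.18, mean -0.17, camera direction up, adjusted p = 0.931). Its member Pik3ip1, an inhibitor of PI3K, stood at 112 ± 20.6 against 201 ± 40.9 CPM, with an adjusted p of 0.416 by edgeR and 0.00443 by DESeq2 (up to 0.917 over the alternatives run for genes).

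The list of TH1 and cytotoxic effector genes did not pass. Of 22 tested members 12 were higher and 10 lower in sign (median 0.07, mean 0.15, camera direction down, adjusted p = 0.931). Tbx21, the transcription factor gene of the TH1 lineage, stood at 44.0 ± 13.6 against 48.4 ± 25.4 CPM, and Ifng at 53.4 ± 16 against 44.1 ± 17 CPM. Prdm1, whose product Blimp-1 opposes Bcl6, was at 0.437 ± 0.505 CPM in control, with 2 libraries at 0, and at 9.93 ± 11.7 CPM in anti-ICOSL cells. The genes of the sorting markers CD4 and CD44 had log2 fold changes of -0.23 ± 0.08 and -0.65 ± 0.29.

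Of 23 tested genes of TCR-induced early activation, 16 were lower and 7 higher in sign, with a median of -0.29. Fry gave an adjusted p of 0.0131 for a shift of this list downward, while camera gave 0.0704 (adjusted p = 0.343 with an estimated correlation, and 0.0131 to 0.355 over the 13 alternatives). Cd69 alone passed when adjusted over the list alone (edgeR adjusted p = 0.0294). The list's mean log2 CPM was 4.21 to 4.59 in anti-ICOSL replicates 7, 9 and 10 but 5.35 in replicate 8, beside 5.48 to 5.69 in control. That mean was lower in the anti-ICOSL group for every list tested but the ribosomal (0.214 higher) and mitochondrially encoded ones (0.0628 higher). The difference was -0.945 for this list, -1.11 for apoptosis and -0.435 for the mTORC1 and MYC programme. It therefore does not single out activation genes. In the AP-1 and heat shock list, with 14 of 25 tested members lower in sign (median -0.13, adjusted p = 0.316 by camera, 0.0123 to 0.971 over the 13 alternatives, past the threshold only without anti-ICOSL replicate 7), the heat shock chaperone genes Hspa1b and Hspa1a passed when adjusted over the list alone (edgeR adjusted p = 0.00389 for each). Hspa1b stood at 1292 ± 622 against 216 ± 68.5 CPM and Hspa1a at 678 ± 351 against 117 ± 43.3 CPM, with log2 fold changes of -2.58 ± 0.39 and -2.53 ± 0.41. These near-identical copies lie next to each other on chromosome 17 of mm10 (34956436 to 34959238 and 34969190 to 34972156, minus strand), and Gm20481 overlaps Hspa1a on the other strand, so their separate counts are uncertain.

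Cytosolic ribosomal protein genes rose relative to all other genes by camera (adjusted p = 4.28e-11, and adjusted p = 0.549 with an estimated correlation), with 68 of 76 tested members higher in sign and a median log2 fold change of 0.25. Their mean log2 CPM was 6.68 and 6.49 in anti-ICOSL replicates 9 and 10, but 6.19 and 6.07 in replicates 7 and 8, beside 6.04 to 6.23 in the control libraries. Over all genes and over the list alone, 0 members passed edgeR's test, and fry gave an adjusted p of 0.303 (4.56e-16 to 0.549 over the 13 alternatives). None of the lists tested passed camera with an estimated correlation.

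**Figure D2:**
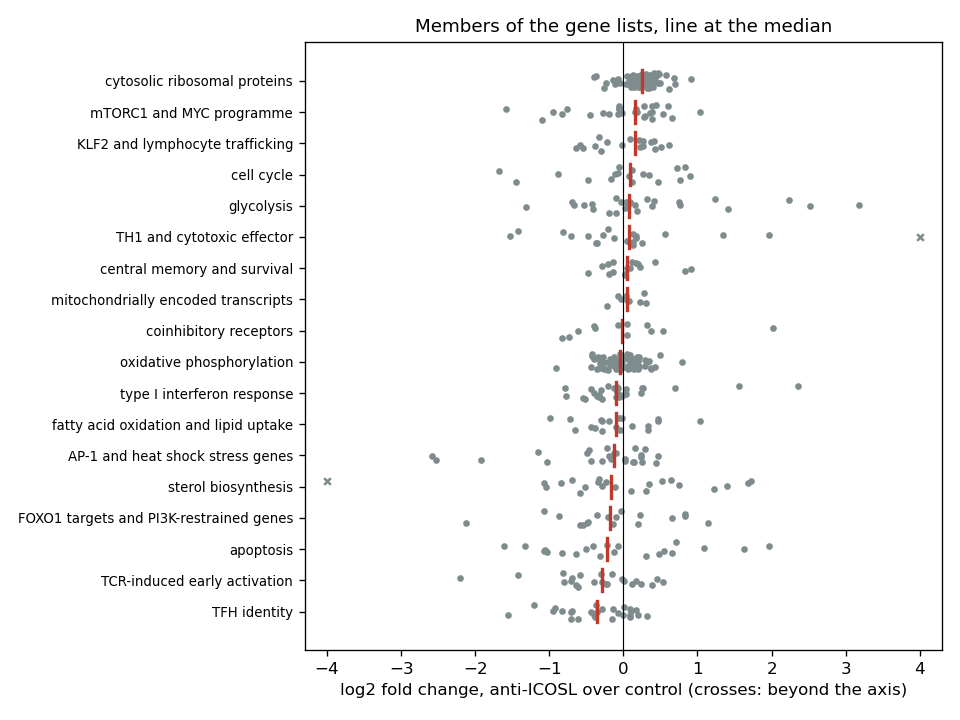
Log2 fold change of anti-ICOSL over control for each tested member of the 18 lists of biology, with 1 point per gene and a red line at the list's median. TFH identity has the lowest median, -0.35, and the cytosolic ribosomal proteins the highest, 0.25.

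The 5 genes with the smallest p in each direction, all with groups that did not overlap and none past the adjusted threshold, were Socs1, Bcl2, Plekhg2, Traj31 and Jmjd6 on the higher side and Camkk1, Lamc1, Emp1, Gpnmb and Klf10 on the lower. Plekhg2 stood at 88.1 ± 13.3 against 180 ± 33.5 CPM, and Jmjd6, whose reads could include those of Mettl23 on the other strand, at 96.7 ± 11.8 against 176 ± 32.6 CPM. Traj31, a joining segment of the T cell receptor alpha chain, stood at 1.62 ± 1.2 against 40.7 ± 27.4 CPM. Camkk1, Lamc1, Emp1 and Gpnmb had 11.1 to 17 CPM in control and no read in any anti-ICOSL library, at least 163-fold lower for Emp1 and at least 250-fold lower for Gpnmb against the floor of 3 counts per library. That floor covers counting error only. Of genes read in every control library at a mean of 10 to 50 CPM, an anti-ICOSL library lacked 5.23% on average. That rate is per library and does not give the rate of absence from all 4. Of 15580 genes read in every control library, 115 were absent from all 4 anti-ICOSL libraries. Whether such absences come from the cells or from the libraries is open, so these folds do not bound a difference between the cells. Klf10, a transcription factor gene induced by TGF-beta, stood at 31.3 ± 11.8 against 3.31 ± 0.671 CPM.

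In mm10 Cxcr5 (ENSMUSG00000047880) lies on chromosome 9 from 44511787 to 44561877 on the minus strand and overlaps Bcl9l on the other strand. Bcl6 (ENSMUSG00000022508) lies on chromosome 16 from 23965052 to 23988852, Socs1 (ENSMUSG00000038037) on chromosome 16 from 10782240 to 10785536 and Bcl2 (ENSMUSG00000057329) on chromosome 1 from 106538178 to 106714274, all on the minus strand. Bcl6 overlaps Gm37419, and Bcl2 overlaps D630008O14Rik, on the other strand, so their counts too are uncertain to that extent.

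Fewer genes were detected in the anti-ICOSL libraries, 16020 to 17636 with at least 1 read against 18645 to 19485 in control (two-sided exact permutation p = 0.0286, adjusted p = 0.4 over 14 library measures, the first being the smallest p this design allows). With at least 10 reads the ranges were 13958 to 15436 and 16374 to 17051. The anti-ICOSL libraries were also less alike, with Spearman correlations across genes of 0.773 to 0.822 between them against 0.91 to 0.934 between controls, and a common dispersion of 1.39 against 0.421. The 100 most abundant genes took 19.0% ± 0.336 of counts in anti-ICOSL and 19.1% ± 0.423 in control libraries. Mitochondrially encoded transcripts took 0.868% ± 0.0147 and 0.839% ± 0.0326.

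**Figure D3:**
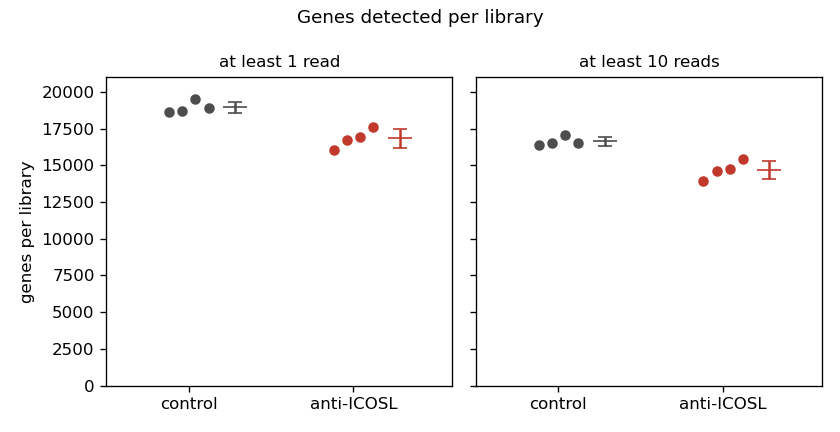
Genes per library with at least 1 read (left) and at least 10 reads (right), with 1 point per library, a bar at the group mean and whiskers of 1 SD. The anti-ICOSL libraries reach 17636 genes at most with at least 1 read, below the lowest control at 18645.

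None of the summed levels of cell type markers passed (14 library measures in all, adjusted p at or above 0.4 by exact permutation), and with the smallest p at 0.0286 none could have passed alone. T cell markers summed to 18710 ± 905 CPM in control and 16730 ± 823 CPM in anti-ICOSL libraries (exact permutation p = 0.0571). Regulatory T cell markers summed to 624 ± 142 and 532 ± 71.7 CPM, CD8 T and NK cell markers to 20.4 ± 7.28 and 8.43 ± 7.14 CPM (exact permutation p = 0.0857), and myeloid cell markers to 98.6 ± 30.4 and 102 ± 60.0 CPM. B cell markers summed to 1682 ± 109 and 1554 ± 394 CPM, mostly from Ighm at 1163 ± 116 and 1209 ± 271 CPM. Plasma cell markers, mostly Xbp1, summed to 221 ± 21.5 and 176 ± 75.1 CPM, dendritic cell markers, mostly Cst3, to 109 ± 23.3 and 112 ± 53.0 CPM, and stromal and endothelial cell markers, mostly Pecam1, to 179 ± 40.5 and 170 ± 51.8 CPM. Erythroid and platelet markers summed to 8.90 ± 12.4 and 106 ± 207 CPM, the second resting on anti-ICOSL replicate 10. By camera the lists of T cell, regulatory T cell, B cell and myeloid markers did not pass (adjusted p = 0.457, 0.664, 0.178 and 0.859, the last with direction down against a median of 0.26), and the other lists of cell types had fewer than 5 tested members. Adjusted over the list alone, 1 B cell marker passed edgeR's test, Cd22 (log2 fold change -0.74, adjusted p = 0.0444), named here after its value was seen.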

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

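The split counts for edgeR, the test of TH1 cells in replicates 7 and 9 and the tests on Hspa1a and Hspa1b were chosen only after the results were seen, as were the comparisons of the tests themselves with other groupings of the libraries.

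A single library stood far from the other 3 of its group in 15 of 200 groups of 4 values tested, where chance gives about 10. Erythroid and platelet markers summed to 416 CPM in anti-ICOSL replicate 10, with 3.46 CPM in the next library. In the control group, plasma cell markers were low in replicate 1 at 189 CPM and myeloid cell markers high in replicate 3 at 144 CPM. Single control libraries stood apart for Hspa1a (1201 CPM, replicate 4), Pdk1 (137 CPM, replicate 4), Camkk1 (10.1 CPM, replicate 4), Il18r1 (15.2 CPM, replicate 1), Gpi1 (218 CPM, replicate 1), Tsc22d3 (112 CPM, replicate 3), Slc3a2 (236 CPM, replicate 3) and Kif20a (31.3 CPM, replicate 3). In the anti-ICOSL group these were Tcf7 (1718 CPM, replicate 7), Cd44 (383 CPM, replicate 8), Rps9 (364 CPM, replicate 8) and Idi1 (0.187 CPM, replicate 8, with the other 3 at 0).

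The first pattern is the lower number of genes detected in the anti-ICOSL libraries. Read depth argues against itself as the cause, since after thinning every library to the smallest total the lowest control still exceeded the highest anti-ICOSL library by 974 genes. The 100 most abundant genes took no larger share of the counts (difference of means -0.10 percentage points, anti-ICOSL minus control). Fewer starting molecules stays open: 115 genes read in all 4 controls were absent from all 4 anti-ICOSL libraries, 23.8 times the number under independent loss at the same abundance, and a ratio above 3 had been set as evidence against it. That bound was wrong, because over the 70 choices of 4 reference libraries the ratio ran from 5.7 to 81.8 with a median of 23.5, so this explanation and an effect of the antibody cannot be told apart with these counts; cell numbers per sort were not analysed here.

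The second pattern is the lower TFH identity list. A general loss of transcripts at the same abundance stays open. The median of -0.35 lay at percentile 0 of 10000 random lists matched on mean expression. Yet 9 of the 35 splits of the libraries into 4 and 4 left the middle 95% of random lists, so the percentile alone decides nothing. Of the 35 splits, 1, the real one, departed as far from matched lists (-0.344, against 0.249 in the largest other), the smallest share that 35 splits can give. That split also separates the libraries by genes detected, so a general loss could put it first too. The comparison therefore cannot decide on that explanation. Chance is not excluded for the camera result, since 3 of the 35 splits, the real one included, gave a camera p as small (0.000362 in the real split, 7.25e-05 in the most extreme other). The others put control replicate 1 with anti-ICOSL replicates 7, 9 and 10 or with 8, 9 and 10. They thus keep much of the real grouping. Admixed TH1 cells, which the gate on Ly6C and PSGL-1 should remove, stay open. Admixture was to put the summed CPM of Ly6c1, Ly6c2, Ccl5, Nkg7, Cxcr6 and Gzmb above every control in every anti-ICOSL library, which was not met. The sum was 26.4, 46 and 34.4 CPM in replicates 7, 9 and 10, against 71.9 CPM in the lowest control. Replicate 8 held 187 CPM (1.27 times the highest control), with Cxcr6 at 178 CPM, and had the highest anti-ICOSL TFH score, 7.50. Without Cxcr6 the sums were 0.874 and 2.4 CPM in replicates 7 and 9, against 4.67 CPM in the lowest control. Replicate 10 held 19.3 CPM without Cxcr6, against 16.5 CPM in the highest control. Replicates 7 and 9 (at most 0.64 times the lowest control) were singled out because both of their sums were low, so their test decides nothing. An effect of anti-ICOSL on these genes is a hypothesis that could account for the pattern, while chance, a general loss of transcripts and admixture stay open beside it.

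The third pattern is the lower level of Hspa1a and Hspa1b. A different split of reads between the copies is argued against by their sum, which in the lowest control was 3.13 times that in the highest anti-ICOSL library. Less handling stress stays open, since the median log2 fold change of 9 other heat shock genes was 0.16 (range -0.23 to 0.47), against a mean of -2.56 for the pair, but -0.06 with 6 of 9 lower in sign without anti-ICOSL replicate 7, and 10 of 14 immediate early members of the AP-1 and heat shock list were lower in sign. Of the same family, Hspa1l was lower in every anti-ICOSL library (log2 fold change -2.41, 10.8 ± 4.8 against 2.02 ± 0.785 CPM, edgeR adjusted p = 0.5). An effect of the antibody remains a hypothesis. For these genes it and a difference in handling cannot be told apart, since no batch is given in the sources used here. Members of the stress list went both ways, which does not decide between them.

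Of the 35 splits, 1, the real one, gave as many DESeq2 calls (183, with 101 in the highest other). That met the bound set beforehand against chance. It is also the smallest share that 35 splits can give, so chance is made less likely but not excluded for that count. For edgeR's count of 0 (742 at an unadjusted p under 0.05) the comparison says nothing, since all 35 splits give at least 0, the highest other also being 0. Chance is not excluded for the number of lists past camera's threshold, as 16 of the 35 splits gave at least 2 (4 in the highest other). The real split also separates the libraries by genes detected, so the DESeq2 count may reflect library complexity as well as the antibody.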

How the results depend on the processing

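Of the alternatives, the filters on mean CPM, the variance per group, the permutation of list means, the detection limit and the thinning were chosen after seeing the data. The edgeR count of 0 changed genes held in every scaling, with no filter, with the stricter read filter and without each library in turn (0 to 0 genes). It became 183 by DESeq2 (53 higher, 130 lower), 7 lower with 1 surrogate variable, 3 lower at a mean of at least 50 CPM (Hspa1b, Hspa1a and Gm20481, with fewer genes tested) and 32 at an adjusted p under 0.1 (1 higher, 31 lower, 22 of the 32 with no read in any anti-ICOSL library). Apart from the looser threshold and the fewer genes tested, the cause was not tested. The 2 lists past camera's threshold became 0 with an estimated correlation, 1 by fry and 1 to 4 without single libraries (4 without anti-ICOSL replicate 8, 1 without replicate 9 and 1 without replicate 10). Permutation of list means gave 0, which says nothing, since the TFH list reached its smallest p, 0.0286, and yet an adjusted p of 0.126. Over the 13 settings run for lists, TCR-induced early activation passed by fry (0.0131), with the surrogate variable (0.0469) and without control replicate 4 (0.0339) or anti-ICOSL replicate 8 (0.0347), the AP-1 and heat shock list without anti-ICOSL replicate 7 (0.0123) and B cell markers without replicate 8 (0.0462). The adjusted p of the TFH list ran from 0.000737 to 0.343 and that of the ribosomal list from 4.56e-16 to 0.549. Of 86 named genes none passed by edgeR without single libraries, and 20 passed by DESeq2. Tbx21 changed sign without control replicate 1 (-0.04) and anti-ICOSL replicate 9 (range -0.23 to 0.36), and Ccr7 without anti-ICOSL replicate 10 (range -0.17 to 0.49). No list past a threshold changed direction, and of all 22 lists 0 to 7 did so per setting, each short of the threshold. The lower number of detected genes held at a limit of 10 reads and after thinning (exact permutation p = 0.0286 for each), and the sums of markers kept their direction under TMM scaling.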

Other observations

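No test here was chosen only after its own result was seen, but the STAT5 targets were picked after Socs1, Bcl2 and Il7r had been seen to be higher.

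Metabolic genes did not move together. Of 26 tested glycolysis genes 16 were higher and 10 lower in sign (median 0.08, adjusted p = 0.15 by camera), with the glycolytic enzyme genes Gpi1 at 199 ± 12.6 against 259 ± 12.2 CPM and Hk1 at 132 ± 34.8 against 224 ± 52.1 CPM. Oxidative phosphorylation had 34 of 75 tested genes higher in sign (median -0.04, camera direction up, adjusted p = 0.859) and fatty acid oxidation and lipid uptake 6 of 19 (median -0.11, camera direction up, adjusted p = 0.931). Cpt1a, which encodes the enzyme that admits long-chain fatty acids to mitochondria, stood at 69.3 ± 23.8 against 142 ± 20.8 CPM, with groups that did not overlap and an edgeR adjusted p of 0.731. Sterol biosynthesis had 10 of 22 higher in sign (adjusted p = 0.534), with Idi1, of the mevalonate pathway, at 3.82 ± 0.529 against 0.0466 ± 0.0932 CPM. Of 9 tested mitochondrially encoded transcripts 6 were higher in sign (adjusted p = 0.15).

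Growth, death and antiviral lists also fell short of camera's threshold. In the mTORC1 and MYC programme 15 of 28 genes were higher in sign (median 0.16, mean -0.01, camera direction up, adjusted p = 0.457), with the nucleolar gene Nop56 at 167 ± 19.5 against 263 ± 51.8 CPM. In the cell cycle list 10 of 18 were higher (median 0.09, mean -0.02, camera direction up, adjusted p = 0.931), with the mitotic kinesin gene Kif20a at 19.5 ± 7.93 against 7.16 ± 2.10 CPM. For apoptosis 13 of 21 were lower in sign (adjusted p = 0.534), with Casp8, an initiator caspase gene, at 134 ± 18.4 against 187 ± 23.9 CPM and Trp53, which encodes p53, at 227 ± 23.5 against 182 ± 23.6 CPM. The type I interferon response had 20 of 28 lower in sign (adjusted p = 0.664), and coinhibitory receptors 6 of 12 (median -0.02, mean 0.02, camera direction down, adjusted p = 0.859).

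Higher Socs1 and Bcl2 together could be a sign of stronger STAT5 signalling, since both are STAT5 targets. Il7r, also higher, belongs to the list of FOXO1 targets and was not counted as a STAT5 target. Stronger STAT5 signalling was tested as a hypothesis on 9 other STAT5 targets. The result leaves it open: the 8 that were tested had a median log2 fold change of 0.0358 (SD 0.581), 5 of them higher in sign, and camera gave a p of 0.213 (0.449 with an estimated correlation) with direction up. Cish, with the largest change of the 8, stood at 18 ± 12.1 against 53.3 ± 23.1 CPM (log2 fold change 1.57 ± 0.57, groups overlapping, edgeR adjusted p = 1). Pim2, Osm, Mcl1, Ccnd3, Socs3, Pim1 and Ccnd2 had log2 fold changes of 0.21, 0.20, 0.05, 0.02, -0.02, -0.09 and -0.36. Socs2 had too few reads to be tested.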
